A study of Rattus norvegicus with 6 samples.

How the data were processed

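Total RNA of primary rat vascular smooth muscle cells was sequenced in 6 libraries, 3 labelled negative control and 3 labelled siRNA_ANK. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with an Illumina RNA library kit. The files hold whole-number counts per gene as deposited by the authors, with 1 file per library, and are not normalized. Per the submitters' processing notes, featureCounts 1.5.0-p3 and DESeq2 were used with the rat genome build mRatBN7.2. The aligner, the strand setting of the counting and the filters on reads are not given in the sources used here. Without a strand setting, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies can share reads. Each file lists 30945 genes with Ensembl identifiers, symbols, coordinates and lengths. Of these, 385 carry no symbol or Ensembl identifier and held 0.306% to 0.339% of the counts. Coordinates are given as in the files.

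Library totals ranged from 15641259 to 17441548 counts, so that 1 count is worth less than 0.1 CPM. The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 13016 genes; 11945 had no count in any library. Libraries were scaled with TMM factors between 0.979 and 1.02, and CPM values are on that scale. The groups were compared with the robust quasi-likelihood test, two-sided, with no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested. Calls are at an adjusted p under 0.05, and 2-fold calls also need a log2 fold change of at least 1 in size. The SE of a log2 fold change is its size over the square root of the F statistic. The biological coefficient of variation was 7.11%. An exact permutation test of 3 against 3 libraries cannot go below 0.1, so no single-gene permutation p is given.

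In all, 32 gene lists were fixed before the data were examined. Of their 765 entries, 724 were matched to the files by symbol and 590 were tested; the other 41 were not analysed here. Lists with at least 5 tested genes (27 lists) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 0.5, with a preset correlation between genes of 0.01 and adjustment over the 27 lists. The same test with an estimated correlation and the fry test were run beside it. Lists share some members and were not independent of each other. The genes named in the text were set by a rule before the data were examined: the targeted gene and the ankyrins; the 12 largest rises and the 12 largest falls among called genes with a mean of at least 2 CPM, groups that do not overlap and a gene symbol; and, per list, up to 4 called members by smallest adjusted p, or the 2 most abundant members where none was called. Some genes that the rule names are not reported here. Genes outside this rule whose values are given are said to have been chosen after their values were seen. A group with 0 counts would be set against 3 counts over the group; such floors cover counting error only.

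Replicates were compared before use. The chi-square of the counts of 2 libraries of the same group, per degree of freedom, ranged from 2.83 to 12.3 over genes with at least 10 counts, so no pair agreed within sampling noise. The steps were tested on simulated counts with the means, library sizes and spread of these libraries. For siRNA_ANK against negative control, 12882 simulated genes were tested. In them edgeR recovered 74.2% of 66 genes changed 1.5-fold, 93.8% of 65 changed 2-fold and 100% of 64 changed 4-fold. Of its 207 calls, 17 (8.21%) were unchanged genes, a larger share than the adjusted p limit for calls aims at. In the real comparison many more genes were called, 5223 of 13016. Recovery and the share of false calls depend on how many genes change, so these values need not hold there. In the same simulation the raised list of 20 genes passed and 0 of the other 26 lists did. The simulated genes were drawn independently of each other, so lists of correlated genes were not tested in this way.

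The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper quartile scaling in edgeR, no filter beyond 1 count, a filter at a mean of 5 CPM, the replicate number as a block, a correction for gene length by loess with a span of 0.5, both together, a test against a fold of 1.2, and leaving out each library in turn. Leaving out negative control replicate 2 and siRNA_ANK replicate 3 together, and leaving the 20 most abundant genes out of the scaling, were added after seeing the data. All 6 libraries were used in the comparison.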

Results

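RNA sequencing was analysed from 6 libraries of primary rat vascular smooth muscle cells, the contractile cells of the vessel wall. According to the labels, 3 libraries came from cells given a negative control and 3 from cells given an siRNA called siRNA_ANK, and the series title describes cells deficient in ANK. The negative control replicates 1, 2 and 3 held 17441548, 17186072 and 15641259 counts over genes, and the siRNA_ANK replicates 1, 2 and 3 held 17033649, 17065297 and 16020392. Counts were found for 16304 to 16580 of the 30945 genes in each library. The comparison asks which genes differ between the siRNA_ANK and the negative control cells. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which can be technical.

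Ankh was lower in siRNA_ANK cells. This gene encodes the progressive ankylosis protein, a membrane protein needed for the release of pyrophosphate from cells, and its protein is also known as ANK. Ankh (ENSRNOG00000010960, chromosome 2, 78153026 to 78280187 on the plus strand of mRatBN7.2) measured 338, 351 and 367 CPM (counts scaled to library size with TMM factors) in the negative controls and 84.9, 76.7 and 120 CPM in the siRNA_ANK libraries. The means were 352 ± 14.7 and 93.7 ± 22.8 CPM (SD, n = 3), 3.76-fold lower in siRNA_ANK, with a log2 fold change of -1.91 ± 0.16 (SE, edgeR adjusted p = 0.000180), and all 3 siRNA_ANK values lay below all 3 control values. The label could also be read as an ankyrin, a family of adaptors between membrane proteins and the cytoskeleton. Ank2 was 157 ± 2.01 against 138 ± 9.52 CPM (log2 fold change -0.19 ± 0.06, adjusted p = 0.0218), and this call was lost when negative control replicate 1, 2 or 3 was left out (adjusted p = 0.0719, 0.0594 and 0.0507). Ank3 was at 6.58 ± 1.01 and 8.33 ± 0.573 CPM, without passing the threshold (adjusted p = 0.0847). Ank1 had 0 to 4 counts in each library and was not tested.

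**Figure D1:**
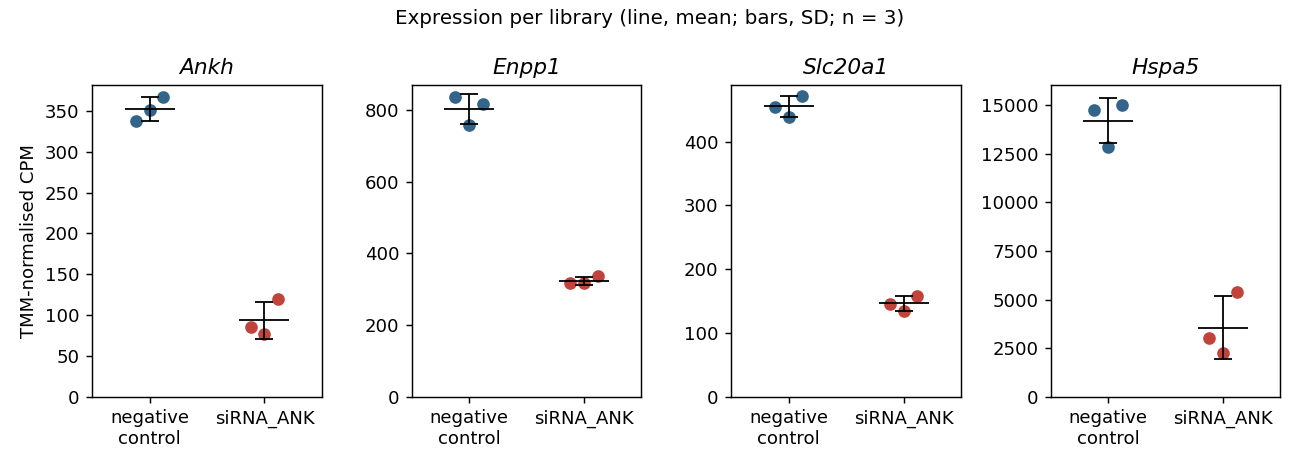
TMM-normalised CPM (vertical axes, each from 0) of Ankh, Enpp1, Slc20a1 and Hspa5 in the negative control and siRNA_ANK libraries; points are libraries, the long line is the mean and the bars are the SD (n = 3). The siRNA_ANK values of Ankh lie between 76.7 and 120 CPM, all below the control values of 338 to 367 CPM, and siRNA_ANK replicate 3 is the highest siRNA_ANK library for Ankh and Hspa5.

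Gene expression differed widely between the groups. Of 13016 genes tested, 2594 were higher and 2629 lower in siRNA_ANK at an adjusted p under 0.05, which is 40.1% of the genes tested. At least 2-fold changes were found for 594 higher and 336 lower genes. The median log2 fold change over all genes tested was 0.01, and the median size of the change among changed genes was 0.46. The values of the groups did not overlap for 51.1% of the genes tested, where chance gives 10%. On the first principal component, which held 70.6% of the variance, negative control replicate 2 (-26.7) and siRNA_ANK replicate 3 (25.4) lay nearest to the other group, while the other controls were at -36.4 and -39.0 and the other siRNA_ANK libraries at 36.3 and 40.4. Without both of these libraries, a choice made after seeing the data, 3007 genes were higher and 3049 lower.

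Among the largest rises were Omd, which encodes the matrix proteoglycan osteomodulin, Myh3, the embryonic skeletal muscle myosin heavy chain, and Nog, the secreted inhibitor of bone morphogenetic proteins noggin. Omd (chromosome 17, 15060217 to 15068441) rose 34.1-fold from 0.394 ± 0.151 to 13.6 ± 0.467 CPM (n = 3, adjusted p = 6.09e-10). Myh3 rose from 1.60 ± 0.818 to 33.0 ± 4.95 CPM and Nog from 0.258 ± 0.105 to 5.06 ± 0.396 CPM. The ligand gene Tnfsf18 rose 12.8-fold from 4.96 ± 0.680 to 64.0 ± 6.88 CPM, the chemokine gene Cxcl12 rose 11.2-fold, and Edn1, which encodes the vasoconstrictor endothelin, rose 9.78-fold. The other genes among the 12 largest rises were Fam169b, Zdhhc23, Fras1, Rasgrp3, Rgs4 and Grip2, between 9.86-fold and 18.3-fold higher. Without negative control replicate 2 the log2 fold change of Grip2 was 4.40 instead of 3.30.

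The largest falls included Reln, which encodes the secreted glycoprotein reelin, Ptprn, a protein of dense-core secretory vesicles, and Ednrb, a receptor for endothelins. Reln (chromosome 4, 12736130 to 13162211) fell 20.1-fold from 57.9 ± 6.59 to 2.87 ± 0.632 CPM (n = 3, adjusted p = 3.62e-11). Ptprn was 84.0 ± 7.10 CPM in the controls and 9.04 ± 0.373 CPM in siRNA_ANK (adjusted p = 1.52e-11), and Ednrb was 13.0 ± 2.83 and 1.42 ± 0.714 CPM. Derl3, which acts in the degradation of misfolded proteins of the endoplasmic reticulum, fell 12.8-fold from 73.9 ± 11.8 to 5.80 ± 2.98 CPM. Ctsw was 38.8-fold lower, with 216 counts over the controls and 5 over the siRNA_ANK libraries, and its log2 fold change moved from -5.28 to -5.94 without siRNA_ANK replicate 2. Mcoln3, Cdhr1, Gldn, Ccbe1, Atp13a4, Kcna4 and C2cd4b, also among the 12 largest falls, were between 7.50-fold and 19.9-fold lower. Without siRNA_ANK replicate 3 the log2 fold changes of C2cd4b and Kcna4 moved from -2.91 and -2.91 to -3.87 and -3.61.

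Genes of the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, fell together in siRNA_ANK. Of 21 members tested, 20 fell and none rose (21 and 0 adjusted over the list alone), with a median log2 fold change of -1.33, and 15 fell at least 2-fold. Atf6, a stress sensor of the endoplasmic reticulum, fell from 419 ± 14.1 to 220 ± 24.7 CPM (log2 fold change -0.93 ± 0.07, adjusted p = 3.13e-07). Edem1, a factor in the disposal of misfolded glycoproteins, fell from 488 ± 42.2 to 175 ± 26.7 CPM, the chaperone gene Canx from 1466 ± 99.8 to 939 ± 81.0 CPM, and Ern1, which encodes the sensor IRE1, 1.74-fold. Hspa5, the main chaperone of the compartment, was chosen after its values were seen; it was 14770, 12878 and 15003 CPM in the controls and 3028, 2271 and 5376 CPM in siRNA_ANK (log2 fold change -1.998 ± 0.38, adjusted p = 0.0168). Its call was lost without negative control replicate 1 or 3 or siRNA_ANK replicate 1 (adjusted p = 0.0534, 0.0550 and 0.0630). The list was lower by camera (adjusted p = 1.22e-10), with an adjusted p = 0.510 with an estimated correlation. The median of the list against the control mean was -1.47, -1.65 and -1.05 in siRNA_ANK replicates 1, 2 and 3, and 0.05, -0.16 and 0.09 in the controls. The ATF4 and integrated stress response list, which covers the branch that limits translation, was not shifted: 7 of 21 members rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.705). Ddit3, which encodes the transcription factor CHOP, fell from 725 ± 55.9 to 240 ± 60.6 CPM, whereas Cebpb, Vldlr and Ddit4 rose 1.48-fold, 1.38-fold and 1.32-fold. Without negative control replicate 1 or 3 the number of its members that fell was 3, and without siRNA_ANK replicate 3 the direction of the list turned (adjusted p = 0.661).

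**Figure D2:**
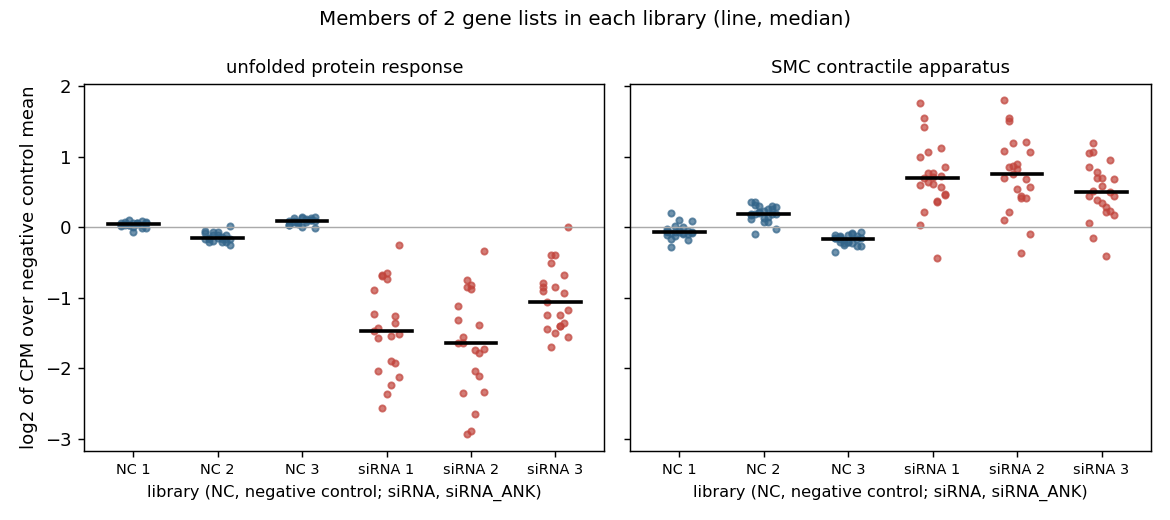
Each point is a member of the unfolded protein response list (left) or the smooth muscle contractile list (right) in 1 library, as log2 of its CPM over the negative control mean (vertical axis); the black line is the median of the list and the horizontal axis gives the 6 libraries. The unfolded protein response medians are -1.47, -1.65 and -1.05 in the siRNA_ANK libraries, and the contractile medians are 0.70, 0.76 and 0.51.

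Genes of the smooth muscle contractile apparatus rose. Of 23 members tested, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.64. Synpo2, an actin-binding protein, rose 2.80-fold from 7.87 ± 2.03 to 22.1 ± 2.90 CPM (log2 fold change 1.49 ± 0.16, adjusted p = 1.61e-05), tropomyosin Tpm1 rose 1.72-fold from 555 ± 79.4 to 952 ± 59.2 CPM, and Ppp1r14a, an inhibitor of myosin phosphatase, rose 1.55-fold. Acta2, Myh11 and Myocd, chosen after their values were seen, encode smooth muscle actin, smooth muscle myosin heavy chain and the transcriptional coactivator myocardin. Acta2 was 1344 ± 280 and 2882 ± 250 CPM, Myh11 276 ± 58.3 and 711 ± 120 CPM, and Myocd 8.56 ± 2.35 and 26.6 ± 7.16 CPM (adjusted p = 0.00203, 0.00362 and 0.00297). The member that fell, also chosen after its values were seen, was Srf, the transcription factor that binds myocardin, from 76.2 ± 4.44 to 57.5 ± 1.36 CPM. The list was higher by camera (adjusted p = 1.10e-05), with an adjusted p = 0.514 with an estimated correlation. Adventitial fibroblast markers were also higher: 8 of 13 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0109, and adjusted p = 0.349 with an estimated correlation). Lum rose from 47.2 ± 3.44 to 97.3 ± 5.58 CPM, Scara5 from 1.86 ± 0.250 to 5.87 ± 0.880 CPM and Dcn from 11.8 ± 0.222 to 17.7 ± 1.16 CPM, and Mfap5 fell 1.40-fold. With the filter at a mean of 5 CPM, only 5 of these markers were tested, 3 of them higher and 1 lower, and the call of the list was lost (adjusted p = 0.171).

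Growth factors and receptors that act on smooth muscle cells were mostly higher, with 20 of 30 members up and 3 down (20 and 3 adjusted over the list alone; camera adjusted p = 4.44e-05, and adjusted p = 0.349 with an estimated correlation). Agtr1a, an angiotensin II receptor, rose 4.29-fold from 46.7 ± 0.909 to 201 ± 9.35 CPM (log2 fold change 2.10 ± 0.06, adjusted p = 1.52e-11). Igf1 rose 3.67-fold and Pdgfd 2.28-fold, and Edn1 belongs to this list too. TGF-beta and BMP targets were higher (16 of 25 rose and 3 fell, with the same counts adjusted over the list alone; camera adjusted p = 0.000623, and adjusted p = 0.349 with an estimated correlation). Id2 and Id3, which encode inhibitors of DNA binding, rose 5.27-fold and 1.99-fold, and Inhba, a subunit of activin, fell 2.21-fold. Of 19 YAP and mechanical targets, 13 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.00461, and adjusted p = 0.510 with an estimated correlation). F3, which encodes tissue factor, rose from 20.2 ± 3.42 to 103 ± 7.67 CPM, while Cav1, Amotl2 and Crim1 rose 2.56-fold, 2.35-fold and 1.89-fold. In the NOTCH pathway list, 8 of 13 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0233, and adjusted p = 0.538 with an estimated correlation). The ligand gene Jag1 rose from 91.8 ± 12.8 to 306 ± 53.1 CPM, and the target genes Heyl, Hey1 and Hey2 rose 4.35-fold, 3.13-fold and 1.61-fold. The number that fell was 0 without negative control replicate 2 or 3 or siRNA_ANK replicate 1 or 2, and the camera call was lost with the filter at a mean of 5 CPM (adjusted p = 0.0516). In the WNT pathway list, 9 of 18 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0214, and adjusted p = 0.349 with an estimated correlation). Dkk3, Lgr6 and Sfrp2 rose 1.93-fold, 3.90-fold and 3.29-fold, and the transcription factor gene Lef1 fell 8.40-fold from 1.25 ± 0.0663 to 0.144 ± 0.0990 CPM, with a log2 fold change of -3.07 that became -3.70 without siRNA_ANK replicate 3.

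Collagens and other matrix proteins moved in both directions with more rises: 22 of 39 rose and 9 fell (22 and 10 adjusted over the list alone; camera adjusted p = 0.0109, and adjusted p = 0.583 with an estimated correlation). Eln, which encodes elastin, was the most abundant gene in each library and rose from 22683 ± 2601 to 65268 ± 1633 CPM (log2 fold change 1.52 ± 0.07, adjusted p = 8.51e-09). It held 2.11% to 2.59% of the counts in the controls and 6.26% to 6.53% in siRNA_ANK. Fbln5, a protein of elastic fibre assembly, rose 2.62-fold, Col11a1 2.35-fold and Mfap4 1.97-fold. Matrix proteases and inhibitors were not shifted as a list (11 of 19 rose and 6 fell, also when adjusted over the list alone; camera adjusted p = 0.261). Adamts9 rose 2.88-fold and Mmp23 1.76-fold, while Plat, which encodes tissue plasminogen activator, fell from 138 ± 0.941 to 62.0 ± 0.573 CPM and Ctsk, the collagen-degrading cathepsin K, fell 1.57-fold.

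Genes of pyrophosphate and phosphate handling changed in both directions, and the list was not shifted by camera (4 of 13 rose and 5 fell, 4 and 7 adjusted over the list alone; adjusted p = 0.358, and adjusted p = 0.538 with an estimated correlation), although a camera test on the DESeq2 Wald statistic placed it past the threshold, lower (adjusted p = 0.0211). The fry test, which tests the members on their own and not against the other genes, called the list lower (adjusted p = 0.000479). Slc20a1, a sodium-dependent phosphate transporter, fell from 455 ± 16.4 to 146 ± 11.8 CPM (log2 fold change -1.64 ± 0.06, adjusted p = 2.28e-10). Enpp1, the ectoenzyme that makes pyrophosphate from extracellular ATP, fell from 803 ± 40.8 to 324 ± 11.1 CPM (log2 fold change -1.31 ± 0.06, adjusted p = 5.93e-10). The phosphate exporter gene Xpr1 fell 1.83-fold and Vkorc1, an enzyme of the vitamin K cycle, rose 1.69-fold. Mgp, which encodes a vitamin K-dependent inhibitor of calcification and was chosen after its values were seen, rose from 421 ± 73.1 to 857 ± 73.0 CPM (adjusted p = 0.000364). The osteogenic and chondrogenic list was not shifted either (4 of 15 rose and 3 fell, with the same counts adjusted over the list alone; camera adjusted p = 0.358). Its cartilage proteoglycan gene Acan fell from 114 ± 4.22 to 31.3 ± 2.04 CPM and Spp1, which encodes osteopontin, from 5982 ± 432 to 2592 ± 217 CPM. Bmp4 rose from 64.8 ± 2.90 to 138 ± 8.79 CPM and Bmp6 from 6.96 ± 1.26 to 29.8 ± 3.45 CPM. Runx2, an osteogenic transcription factor chosen after its values were seen, was 31.7 ± 2.47 and 15.9 ± 2.76 CPM (adjusted p = 1.11e-05). Of 11 purinergic and adenosine receptor genes and their partners, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.286); the median of this list (-0.15) and its mean (0.01) differ in sign, and the median was 0.03 without siRNA_ANK replicate 2. Slc29a1, a nucleoside transporter, Ada, which encodes adenosine deaminase, and the receptor gene P2ry4 fell 2.29-fold, 2.27-fold and 1.73-fold. The receptor gene P2ry2 rose 1.38-fold. The other member that rose did so at least 2-fold, and the largest log2 fold change in the list was 3.23.

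**Figure D3:**
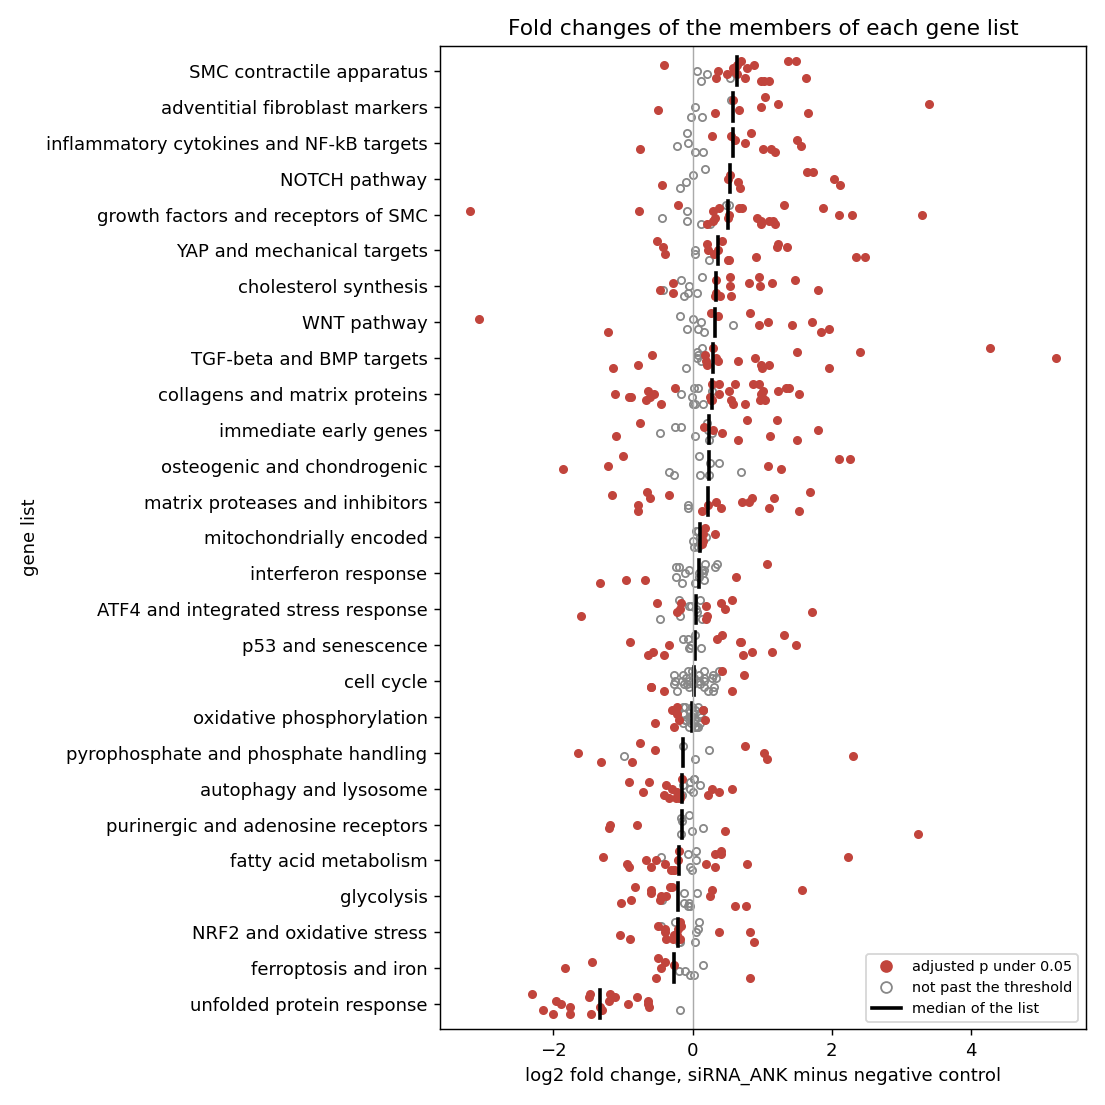
Log2 fold change of siRNA_ANK minus negative control (horizontal axis) for each tested member of the 27 gene lists with at least 5 tested genes (vertical axis, ordered by median); filled points passed an adjusted p under 0.05, open points did not, and the black line is the median of the list. The unfolded protein response has the lowest median (-1.33) and the smooth muscle contractile list the highest (0.64).

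Inflammatory cytokines and NF-kB targets were higher (10 of 16 rose and 1 fell, also when adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.514 with an estimated correlation). Vcam1, a leukocyte adhesion molecule, rose from 269 ± 14.9 to 590 ± 41.0 CPM, Icam1 rose 1.53-fold and Tnfaip3 2.02-fold, and the cyclooxygenase gene Ptgs2 fell 1.69-fold. The NRF2 and oxidative stress list was lower (3 of 25 rose and 14 fell, 3 and 15 adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.538 with an estimated correlation). The peroxidase genes Gpx3 and Gpx4 fell 1.87-fold and 1.32-fold, while Gclc, of glutathione synthesis, and Prdx6 rose 1.77-fold and 1.30-fold. Among 13 ferroptosis and iron genes, 1 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0214, and adjusted p = 0.510 with an estimated correlation). Steap3, a ferrireductase, fell 3.56-fold from 75.2 ± 7.31 to 21.1 ± 2.23 CPM, Acsl4 fell 1.43-fold and Lpcat3 1.37-fold, and the transferrin receptor gene Tfrc rose 1.77-fold; the number that rose was 2 without siRNA_ANK replicate 3. The ferritin light chain symbol Ftl1 stands on several rows of the files, so its counts are uncertain.

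Autophagy and lysosome genes were lower (4 of 25 rose and 12 fell, 4 and 13 adjusted over the list alone; camera adjusted p = 0.0351, and adjusted p = 0.514 with an estimated correlation). Ctsb fell from 823 ± 23.2 to 503 ± 8.61 CPM, the autophagy receptor gene Sqstm1 from 957 ± 31.5 to 510 ± 78.6 CPM, and Map1lc3b and Neu1 1.55-fold and 1.33-fold. This camera call was lost without negative control replicate 1 or siRNA_ANK replicate 1 (adjusted p = 0.0586 and 0.0520) and with the filter at a mean of 5 CPM (adjusted p = 0.0633). Glycolysis genes were lower (5 of 22 rose and 10 fell, also when adjusted over the list alone; camera adjusted p = 0.0361, and adjusted p = 0.349 with an estimated correlation). The enolase genes Eno1 and Eno2 fell 1.51-fold and 1.84-fold, the pyruvate kinase gene Pkm fell from 1380 ± 29.7 to 779 ± 91.2 CPM, and Pfkfb3 rose 1.71-fold. The call was lost without negative control replicate 2 (adjusted p = 0.0557), without siRNA_ANK replicate 3 (adjusted p = 0.0540) and without both (adjusted p = 0.0865). Cholesterol synthesis genes were higher (13 of 23 rose and 3 fell, also when adjusted over the list alone; camera adjusted p = 0.0294, and adjusted p = 0.594 with an estimated correlation). Dhcr7, of the last steps of the pathway, rose from 8.58 ± 1.14 to 29.9 ± 6.53 CPM, and Idi1 and Fdft1 rose 2.76-fold and 1.75-fold; the call of the list was lost without siRNA_ANK replicate 2 (adjusted p = 0.0526). Fatty acid metabolism was not shifted by camera (7 of 25 rose and 12 fell, also when adjusted over the list alone; adjusted p = 0.0977, and adjusted p = 0.514 with an estimated correlation), but was past the threshold, lower, on the DESeq2 Wald statistic (adjusted p = 0.00722). The desaturase gene Scd fell from 412 ± 12.7 to 169 ± 5.94 CPM, and Srebf1, Plin2 and the fatty acid synthase gene Fasn fell 1.88-fold, 1.59-fold and 1.52-fold.

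Several lists were not shifted by camera. Of 35 cell cycle genes, 3 rose and 3 fell (3 and 1 adjusted over the list alone; adjusted p = 0.615). Ccnd1, which encodes cyclin D1, rose from 58.5 ± 6.27 to 97.6 ± 7.56 CPM, and Rrm1 and Tyms, of nucleotide synthesis, rose 1.48-fold and 1.34-fold. Cdk1 was 1.33-fold lower, a call lost without negative control replicate 2 or siRNA_ANK replicate 2 (adjusted p = 0.0783 and 0.0570). Without negative control replicate 2, 8 cell cycle genes rose and 1 fell, without siRNA_ANK replicate 2 none fell (0), and without both negative control replicate 2 and siRNA_ANK replicate 3, 12 rose and 2 fell. Interferon response genes were mixed (2 of 21 rose and 3 fell, 1 and 3 adjusted over the list alone; adjusted p = 0.877), and their median (0.09) and mean (-0.03) differ in sign. The number that rose was 1 without negative control replicate 1 or 3 or siRNA_ANK replicate 1 or 3, and the median was -0.01 without negative control replicate 1. Psmb8, Tap1 and Gbp2, of antigen processing and cell defence, fell 2.52-fold, 1.61-fold and 1.95-fold, and Ifit2 rose 1.54-fold. In the p53 and senescence list, 9 of 21 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.353). The cell cycle inhibitor genes Cdkn2b and Cdkn1a rose 2.47-fold and 1.81-fold, and Btg2 and Fas rose 2.80-fold and 2.20-fold. Of 19 immediate early genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0589, and adjusted p = 0.594 with an estimated correlation), and the list was past the threshold without negative control replicate 2 or siRNA_ANK replicate 2 (adjusted p = 0.0173 and 0.0347) and with no filter (adjusted p = 0.0474). The number that fell was 1 without negative control replicate 2 or 3 or siRNA_ANK replicate 2. Fos, Fosb and Nr4a1 rose 2.83-fold, 2.16-fold and 2.32-fold, and Myc 1.23-fold.

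Nuclear genes of oxidative phosphorylation changed little: 2 of 36 rose and 6 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.539). Cycs fell from 68.2 ± 4.09 to 47.1 ± 8.20 CPM, and Cyc1 fell from 94.0 ± 4.07 to 78.4 ± 5.51 CPM and Uqcrq 1.23-fold. The number that rose was 0 without negative control replicate 1 or 3 and 1 without siRNA_ANK replicate 1 or 2, and 3 members fell without negative control replicate 1. Of the 13 mitochondrially encoded genes, 5 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0635, and adjusted p = 0.554 with an estimated correlation). The number that rose was 2 without negative control replicate 1, 0 without negative control replicate 3, and 1 without siRNA_ANK replicate 1 or 2, and it was 8 after the gene length correction, where the list passed the threshold (adjusted p = 0.0152). Mitochondrially encoded transcripts took 3.08% to 3.28% of the counts in each library and ribosomal protein genes 2.54% to 2.85%.

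Markers of other cell types were mostly at low levels, and few could be tested. Of 4 endothelial markers tested, Erg rose from 4.97 ± 1.09 to 18.5 ± 2.61 CPM and Egfl7 fell from 11.3 ± 1.98 to 5.99 ± 0.625 CPM. Of 2 leukocyte and macrophage markers tested, Cd14 fell from 25.2 ± 1.53 to 12.04 ± 2.06 CPM. Both adipocyte markers tested rose, Plin4 from 20.6 ± 1.47 to 37.6 ± 4.47 CPM and Lipe from 0.254 ± 0.0257 to 1.21 ± 0.493 CPM. Of 4 neural and Schwann markers tested, Ncam1 fell from 182 ± 11.7 to 116 ± 8.73 CPM, and of 4 epithelial and mesothelial markers Upk3b rose from 0.740 ± 0.307 to 2.41 ± 0.607 CPM. These counts were the same adjusted over the list alone. The number that fell was 2 for the neural list without negative control replicate 3 or siRNA_ANK replicate 3, and 2 for the endothelial list without siRNA_ANK replicate 3; without both negative control replicate 2 and siRNA_ANK replicate 3 it was 2 for each.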

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

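The alternatives that left out both negative control replicate 2 and siRNA_ANK replicate 3, or the 20 most abundant genes, were chosen after seeing the data. Ankh stayed lower and past the threshold in every alternative run, with log2 fold changes from -2.13 to -1.79. The count of changed genes (5223) stayed within 1.5 times in every alternative, between 4053 without negative control replicate 1 and 6056 without both in-between libraries, and DESeq2 called 4454. The share of the 5223 genes called again ran from 75.9% without negative control replicate 1 to 99.7% with the 20 most abundant genes left out of the scaling. Without negative control replicate 1, 3965 of the 4053 genes called were also called in the main test. The lower share there thus goes mostly with a smaller count. Without both in-between libraries, 4907 of the 6056 genes called were shared with the main test. The count of genes changed at least 2-fold (930) was 480 with the filter at a mean of 5 CPM (309 higher, 171 lower). That filter tested 10020 genes. The count was 2477 when the 2-fold limit was replaced by a test against a fold of 1.2 (1335 higher, 1142 lower). This test sets a lower fold but asks for evidence beyond it, and 860 of the 930 genes passed it. Of the 15 lists called by camera, 0 were called with an estimated correlation, where 2 had an unadjusted p under 0.05. Fry called 20 lists on direction and 27 in either direction. It tests the members of a list on their own, not against the other genes. With 40.1% of the genes tested changed, its calls do not show that a list moved more than other genes. A simulated list of 20 raised genes passed with both correlations. Its genes were drawn independently of each other, whereas the estimated correlation in the unfolded protein response list was 0.869. The simulation therefore does not show how either setting handles correlated genes. On direction, fry called the pyrophosphate and phosphate handling, fatty acid and p53 lists (adjusted p = 0.000479, 0.00318 and 0.00108). It also called the matrix protease and mitochondrially encoded lists (adjusted p = 0.0157 and 0.0244). The main camera test called none of these. The causes of the list changes were not tested.

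The direction turned for lists that were not past the threshold before or after: ATF4 and integrated stress response (adjusted p = 0.661 without siRNA_ANK replicate 3, in a range of 0.538 to 0.811 over single libraries left out, and 0.731 without both in-between libraries), cell cycle (0.817 without negative control replicate 3, in a range from 0.133) and interferon response (0.889 with no filter, 0.988 with the replicate block and gene length correction, 0.840 without both in-between libraries, and 0.646 to 0.951 when single libraries were left out). The cause was not tested. Of 155 named genes past the threshold, 146 stayed past it in every alternative that could be run for them, 9 lost the call in at least 1, and 0 changed sign. Many of these genes were named for small adjusted p or large changes in these same data. Their stability therefore does not stand for all changed genes. The replicate numbers showed no clear pairing of the samples: the correlation of same-numbered deviations was -0.11, 0.17 and 0.07 for replicates 1, 2 and 3. Between unlike numbers it ranged from -0.19 to 0.16. So few libraries do not settle whether the samples were paired. With the replicate number as a block, 5210 genes and 15 lists were called and Ankh was at -1.93 (edgeR adjusted p = 3.13e-08). No scaling alternative moved the share of higher genes by more than 10 percentage points. At this depth, Ank1 and most markers of other cell types could not be tested.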

Other observations

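The tests of in-between libraries, abundant genes, cell makeup and liver X receptors were chosen only after the result was seen, and the tests of gene length, the circadian clock and other splits of the samples were set before. Some clock genes, a group not described above and named here after their values were seen, differed between the groups. Arntl, which encodes the clock activator BMAL1, was 20.9 ± 0.422 CPM in the controls and 55.5 ± 4.43 CPM in siRNA_ANK (n = 3, log2 fold change 1.41 ± 0.08, edgeR adjusted p = 7.59e-09), higher in 3 of 3 libraries. As a hypothesis, the groups may differ in the phase of the circadian clock. It predicts that genes which peak opposite to Arntl are lower. Of 9 such genes tested, 7 were lower and 1, Bhlhe41, higher, and their median log2 fold change was -0.33. Dbp fell from 40.1 ± 1.04 to 20.7 ± 1.77 CPM, and Tef and Nr1d2 had log2 fold changes of -0.67 and -0.55. The Bhlhe41 call was lost with DESeq2 (adjusted p = 0.0606) and without negative control replicate 1, 2 or 3 or siRNA_ANK replicate 1 or 2 (adjusted p = 0.112, 0.0549, 0.0553, 0.0950 and 0.125). No prediction was set for Clock, the partner of Arntl, which was lower (124 ± 5.06 and 88.1 ± 3.46 CPM). The labels give no time of harvest, so a difference in harvest time and an effect of the siRNA both stay open.

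Abcg1, which exports sterols and was chosen after its values were seen, as were Abca1, Arl4c and Apoe, was 7.25 ± 2.09 CPM in the controls and 1.91 ± 0.396 CPM in siRNA_ANK (adjusted p = 3.53e-05), beside the fall of Scd. As a hypothesis, liver X receptors, which activate both genes, could be less active. Of 9 other targets, 3 fell and 0 rose by edgeR, with a median log2 fold change of -0.053. Abca1 fell from 53.6 ± 9.33 to 18.6 ± 0.407 CPM and Arl4c from 8.42 ± 1.64 to 2.41 ± 0.664 CPM, while Apoe was 8.65 ± 0.352 and 8.72 ± 1.25 CPM. The targets that were not called lay on both sides of 0, with log2 fold changes from -0.21 for Abcg4 to 0.38 for Nr1h3. Targets that fell beside targets without a called change leave this undecided.

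The fall of the unfolded protein response list was weighed against technical explanations. A few genes taking more of the counts would lower the rest alike, and the share of counts left to genes outside the 10 most abundant changed by a log2 of -0.091, against the list median of -1.33. Leaving the 20 most abundant genes out of the scaling moved no gene by more than 0.00159 and decides nothing. After the gene length correction, which moved single genes by up to 0.0817, the median was -1.33, which argues against a length trend. The groups themselves, and anything else that differed between the cultures, stay open.

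In the same list, siRNA_ANK replicate 3 and negative control replicate 2 lay towards the other group: with 0 as the mean of the other 2 libraries of the group and 1 as the mean of the other group, their median positions were 0.193 and 0.228. RNA of the other group mixed into a library would move genes alike, but genes at least 8-fold higher in the other group and above 10 CPM there, chosen without that library, lay at 0.0311 (10 genes) and 0.0440 (15 genes), which argues against mixing. Ankh was at 0.143 in siRNA_ANK replicate 3, so a weaker loss of Ankh there may have a part, which 1 library leaves open. In negative control replicate 2 it was at 0.00643, but the other 2 controls are 0.113 apart on this scale, so whether lower Ankh has a part there is open too.

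The rise of contractile genes was weighed against a larger share of smooth muscle cells. That would lower markers of every other cell type alike. Some fell (log2 fold changes of -1.06 ± 0.11 for Cd14, -0.66 ± 0.07 for Ncam1 and -0.92 ± 0.15 for Egfl7) and others rose (1.89 ± 0.16 for Erg, 0.87 ± 0.10 for Plin4 and 1.69 ± 0.34 for Upk3b), on lists of 2 to 4 tested genes whose medians decide little, while adventitial fibroblast markers were at a median of 0.58, with 8 of 13 higher and 1 lower. Markers that move apart do not decide this, because which cells express the tested markers here is not known. Only 4 of 14 endothelial and 2 of 16 leukocyte and macrophage markers could be tested. The fibroblast list lost its camera call with an estimated correlation (adjusted p = 0.349). It also lost it with the filter at a mean of 5 CPM (adjusted p = 0.171, median 0.33 over the 5 genes tested). Its members Dcn and Lum are also expressed by smooth muscle cells. A larger share of smooth muscle cells, a change within the cells and the group itself stay open.

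The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave the largest result in 1 of 10 for each count. It called 5223 genes by edgeR, 930 of them at least 2-fold changed, and 15 lists; among the other 9 splits the highest counts were 0 genes, 0 genes at least 2-fold changed and 12 lists. In those splits, 84 to 467 genes had an unadjusted p under 0.05 and limma-voom called 0. Each of those splits has libraries of both groups on both sides, so the difference between the groups adds to the spread within a side. Their 0 called genes therefore do not show what chance alone would give. The 12 lists came from the split with siRNA_ANK replicate 3 beside negative control replicates 1 and 3.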
